A study of Mus musculus with 58 samples.

How the data were processed

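The counts were read from the deposited table of 24537 genes and 58 libraries. Per the submitters' processing notes the reads were aligned with STAR and counted with HOMER on GRCm38 (mm10), with versions not stated. The values are expected counts (estimated counts), made by the authors: the deposited table's header gives the HOMER command for raw counts over exons, with 1 transcript kept per gene symbol and no strand setting. They come in steps of 0.5, and 29.9% of them are not whole numbers, so they were rounded to whole counts before every count model. Because the counting had no strand setting, reads from an overlapping or antisense gene can be counted for a gene. Reads of close paralogs can be shared, and 393 gene symbols have more than 1 copy. Coordinates are in mm10, starting at 1, as the table gives them. The labels give 2x75 bp reads from polyA RNA (Watchmaker kit, Element AVITI), ruxolitinib at 45 mg/kg by gavage 2 times a day with a break at weekends for 30 days, and the sequencing batch of each library. Median exon counts per group and batch ran from 12.6 M (old Myc vehicle, first batch) to 22.4 M (old Myc ruxolitinib, second batch, 11.9 to 40.98 M). They were 12.7 M in young Myc ruxolitinib and 16.1 M in young mApple vehicle livers. The precision that this depth gives is that of the standard errors printed beside each gene and of the simulated counts described below.

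All work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Each comparison was fitted with edgeR quasi-likelihood on the libraries of its groups, with TMM scaling, filterByExpr with a minimum count of 10, and a batch term where both batches were present. P-values are two-sided and adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. The standard error of a log2 fold change is its absolute value divided by the square root of the F statistic. The last 5 of the 10 comparisons use the second batch alone, because young mice were sequenced only there. Young livers with Myc and vehicle, or with mApple and ruxolitinib, were not analysed here.

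Gene lists (31) were written from general knowledge of liver and interferon biology, and a member absent from the table was left out. Each list was tested with camera, with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation, adjusted over the 31 lists of a comparison. Of the 310 tests, 118 passed with the preset correlation and 5 with an estimated correlation. List counts are given from p adjusted over all genes, and beside them from p adjusted over the list alone. The level of a list in a library is the mean of log2(counts per M + 1) of its members, with TMM scaling over all 58 libraries. Levels were compared by permutation of group labels within batch, exact where all arrangements could be listed and otherwise with 100000 draws. Levels and correlations were also adjusted by Benjamini-Hochberg within their families.

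A gene was named by rule. Myc, Irf7, Isg15, Ifit1, Ifit3, Oasl2 and Usp18 were taken in every comparison, together with the 5 largest increases and 5 largest decreases past the threshold with a mean log2 counts per M of at least 1. Predicted genes, Mup genes and antibody or T cell receptor segments were left out of that choice. Up to 4 members with the smallest p were added from each list. The text prints only a part of the genes this rule names, and of those taken in every comparison 1 is not reported here. A gene outside this rule is said to be chosen after its values were seen.

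The pipeline was tested on simulated counts with implanted changes, made from each gene's mean over the libraries and its fitted dispersion. Genes were drawn independently of each other and without a batch effect. Of genes given a log2 change of 1, 77.8% were found for ruxolitinib in old mApple livers, 80% in old Myc livers, 90% for Myc under vehicle, 73% for the interaction of vector and drug, 75% for age in mApple vehicle livers and 91% for age in Myc ruxolitinib livers. At a log2 change of 2 the shares were 95% to 99%. Of unchanged genes 0.0376% to 0.0741% were called. A shift of -0.5 implanted in the interferon list was found in all 6, with 0 other lists called. Because the simulated genes are independent, this cannot test list calls where genes move together. Nor can it give the rate of false calls under the spread among real livers.

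Alternatives set before the values were read were RLE size factors, DESeq2, limma voom with quality weights, no filter, no batch term, each batch alone and a single fit of all 58 libraries. Others were a pseudocount of 0.1 in place of 1, library totals in place of TMM, Spearman correlation, removal of the 2 libraries farthest from the median, an unadjusted p of 0.05 and leaving out each library in turn. Leaving out library 870, library 858, or libraries 860, 861, 864 and 865 was added after quality measures were seen, as was splitting the vehicle libraries. Group labels were also exchanged within batch to give up to 100 splits of the same libraries. Libraries were kept in the comparisons whatever their quality measures.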

Results

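The 58 libraries come from whole livers of male C57BL/6J mice, 42 old and 16 young (4 months). Each mouse received an AAV8 vector, a virus that enters liver cells, with a TBG promoter that is active in hepatocytes. The vector carried either Myc, a transcription factor that drives growth and can cause liver cancer, or mApple, a red fluorescent protein used as a control. The mice were then given ruxolitinib, an inhibitor of the kinases JAK1 and JAK2, or vehicle by mouth for 30 days. The old groups are Myc with ruxolitinib (14 libraries), Myc with vehicle (11), mApple with ruxolitinib (9) and mApple with vehicle (8). The young groups are Myc with ruxolitinib (10) and mApple with vehicle (6), both sequenced in the second batch. The first batch holds 18 libraries of old mice aged 25 months and the second batch 40, with its old mice aged 24 months, so age among the old mice cannot be told apart from batch.

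The libraries hold 10.68 to 40.98 M (M, 1e6) counts in exons (median 14.6 M), and albumin (Alb) alone takes 9.65% of them. Xist, expressed from the inactive X chromosome of females, stayed at or below 0.680 counts per M (CPM), and the Y chromosome gene Ddx3y at or above 24.8, and the samples are labelled male. Among 164 pairs of libraries within a group and batch, 0 were identical, and the smallest ratio of their difference to counting noise (chi-squared per degree of freedom) was 7.59. The labels call each library a separate sample, so the p-values measure spread among samples of a single experiment. The comparisons, gene lists and main tests were set down before the data were examined, and tests and runs added later are named as such. All p-values are two-sided, gene tests are edgeR with adjustment over all tested genes at a threshold of 0.05, and gene values are log2 fold changes ± standard error. Beside list levels, the share of library pairs (1 from each group, same batch) in which the first-named group was higher is given. Positions are in mm10.

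Myc was measured first because it checks the vector labels. In old livers under vehicle its level, log2(CPM + 1), averaged 5.51 (SD 1.17, n = 11) with the Myc vector and 3.86 (SD 1.21, n = 8) with mApple. The difference within batches was 1.59 (exact permutation p = 0.00514), yet only 4 of the 11 Myc libraries lay above the highest mApple library of both batches, at 5.87. Within batches this was 4 of 6 in the first and 5 of 5 in the second, where the highest mApple library was at 3.90. Under ruxolitinib the levels were 5.34 (SD 0.645, n = 14) and 3.03 (SD 0.90, n = 9), a difference of 2.50 (exact permutation p = 4.76e-06), with 14 of 14 Myc libraries above the highest mApple library. In the first batch alone the vehicle difference was 1.12 (exact permutation p = 0.214), and in the second batch 2.10 (exact permutation p = 0.00794). Library 870, labelled old Myc vehicle, had a Myc level of 2.94, among the mApple values, and without it the vehicle difference was 1.91 (exact permutation p = 0.000126). Library 855, labelled old mApple vehicle, held the highest mApple level. The counts cannot tell vector transcripts from the mouse's own Myc gene (chromosome 15, 61985341 to 61990361).

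**Figure D1:**
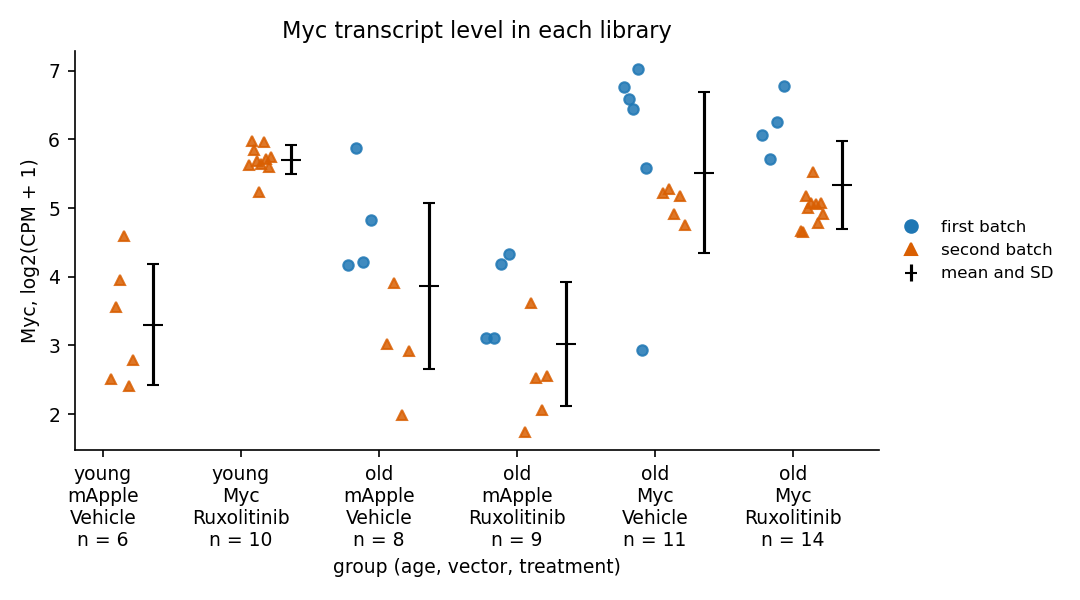
Myc level in each library by group, log2(CPM + 1). Circles are the first batch, triangles the second, and black the mean and SD; the old Myc vehicle libraries span the widest range, and 870 lies among the mApple values.

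The first question is what JAK inhibition changes in aged livers without added Myc. In old livers carrying mApple, genes induced by interferon were lower with ruxolitinib (n = 9) than with vehicle (n = 8). Ifit1 (chromosome 19, 34640889 to 34650009), whose protein binds viral RNA, had the largest decrease (-2.50 ± 0.41, adjusted p = 0.0115; 3.15 ± 1.93 against 16.9 ± 11.3 CPM). Its neighbour Ifit3 (-1.88 ± 0.34, adjusted p = 0.0203), Rtp4 (-1.91 ± 0.23, adjusted p = 9.0e-04), and Irf9 (-1.43 ± 0.14, adjusted p = 1.14e-04), a part of the factor that carries the interferon signal to the nucleus, fell too. Across the transcriptome 53 of 13554 genes changed, 52 down and 1 up.

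Of 48 genes of the type I interferon list, 19 fell and 29 were not past the threshold (35 down with p adjusted over the list alone); median -0.81, camera adjusted p = 4.25e-44, adjusted p = 0.16 with an estimated correlation. Further members that fell were the antiviral GTPases Mx1 (-2.07 ± 0.41) and Mx2 (-1.53 ± 0.20), Ifit3b (-2.03 ± 0.35), Rsad2 (-1.99 ± 0.41), which makes an antiviral nucleotide, and the ADP-ribosyltransferase Parp14 (-1.24 ± 0.17). Values not past the threshold were Usp18, which restrains the interferon receptor, at -1.91 ± 0.44, adjusted p = 0.0844; Oasl2 at -1.40 ± 0.41, adjusted p = 0.228; Irf7 at -0.93 ± 0.33, adjusted p = 0.37; and Isg15 at -0.96 ± 0.41, adjusted p = 0.457. As a level per library, the list differed by -0.81, exact permutation p = 5.67e-04 two-sided, adjusted p = 0.0176, higher in 8.33% of library pairs, with -0.68 in the first batch and -0.93 in the second. In the list of interferon gamma targets and guanylate-binding GTPases (26 genes), 5 fell and 21 were not past the threshold (12 down with p adjusted over the list alone); median -0.76, camera adjusted p = 4.64e-20, adjusted p = 0.16 with an estimated correlation. Irgm2 (-1.80 ± 0.21), Irgm1 (-0.93 ± 0.17), Gbp11 (-1.60 ± 0.28) and the chemokine Cxcl10 (-1.52 ± 0.28) were among those that fell.

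Among 25 core genes of the JAK-STAT pathway 3 fell, namely the signal carriers Stat2 (-0.53 ± 0.10, adjusted p = 0.0236) and Stat3 (-0.69 ± 0.14, adjusted p = 0.0303) and the interleukin 6 co-receptor Il6st (-0.50 ± 0.11, adjusted p = 0.0407). In the list of 20 male-type liver genes that follow growth hormone through STAT5, 1 fell and 19 were not past the threshold (6 down with p adjusted over the list alone); median -0.44, camera adjusted p = 1.97e-10, adjusted p = 0.16 with an estimated correlation. Its level per library differed by -0.70, exact permutation p = 0.0093 two-sided, adjusted p = 0.0721, higher in 19.4% of library pairs, with -1.28 in the first batch and -0.17 in the second. In the first batch the hepatocyte list level differed by -0.425 (0.0943 in the second), and ruxolitinib libraries 864 and 865 had 5.695 and 6.105 for the male-type list and 9.545 and 9.572 for the hepatocyte list, with acute phase (10.32) and neutrophil (5.41) levels high in 864. The member past the threshold was the antitrypsin gene Serpina1e (-0.92 ± 0.17, adjusted p = 0.0203). Myc itself was at -0.87 ± 0.36, adjusted p = 0.454. Calls that single libraries decide are those of Rsad2 (lost without any 1 of 14 of the 17 libraries), Il6st (13), Stat3 (10) and Mx1 (8), of Stat2 without 854, 856 or 863, and of Irgm1 and Cxcl10 without 856. The count of 53 depends on single libraries: 20 genes without 856, 28 without 1139, 28 without 1142, 31 without 1141, 33 without 863 and 34 without 865. Without 1136 the interferon median was -0.49.

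**Figure D2:**
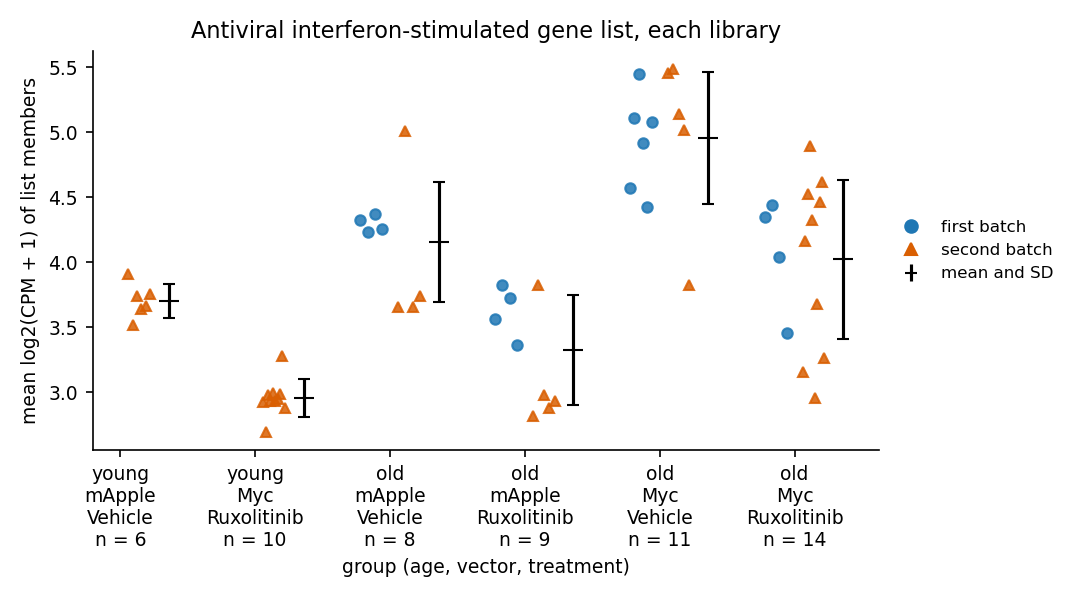
Mean level of the type I interferon list in each library by group, log2(CPM + 1), with circles for the first batch, triangles for the second and black for mean and SD. Old livers averaged 3.33 with mApple and ruxolitinib, 4.16 with mApple and vehicle, 4.02 with Myc and ruxolitinib and 4.95 with Myc and vehicle.

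The next question is what the drug changes in aged livers driven by Myc. In old livers carrying Myc, ruxolitinib (n = 14) against vehicle (n = 11) again came with lower interferon genes. Ifit1 fell (-2.39 ± 0.39, adjusted p = 0.00272; 6.8 ± 4.43 against 35.8 ± 22.6 CPM), as did Ifit3 (-1.88 ± 0.35, adjusted p = 0.00756) and Usp18 (-1.87 ± 0.33, adjusted p = 0.00439). Direct STAT5 targets fell as well: Socs2 (chromosome 10, 95411490 to 95416857; -2.47 ± 0.30, adjusted p = 1.41e-04; 3.03 ± 1.47 against 16.6 ± 10.6 CPM) and Cish (-2.09 ± 0.44, adjusted p = 0.0202) both encode feedback inhibitors of cytokine receptors. Of 13749 genes 75 changed, 69 down and 6 up.

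Of 48 type I interferon genes, 21 fell and 27 were not past the threshold (34 down with p adjusted over the list alone); median -0.94, camera adjusted p = 5.42e-41, adjusted p = 0.0823 with an estimated correlation. Stat2 (-0.66 ± 0.10), Parp9 (-0.77 ± 0.13) and Parp14 (-1.03 ± 0.17) fell. Isg15 (-1.27 ± 0.41, adjusted p = 0.203), Oasl2 (-0.95 ± 0.47, adjusted p = 0.367) and Irf7 (-0.48 ± 0.34, adjusted p = 0.507) were not past the threshold. The list level differed by -0.93, exact permutation p = 9.56e-04 two-sided, adjusted p = 0.00741, higher in 9.46% of library pairs. In the interferon gamma list (26 genes), 8 fell and 18 were not past the threshold (17 down with p adjusted over the list alone); median -0.98, camera adjusted p = 3.68e-22, adjusted p = 0.0823 with an estimated correlation. The immunity-related GTPases Igtp (-1.65 ± 0.24), Irgm1 (-1.12 ± 0.18), Iigp1 (-1.05 ± 0.17, adjusted p = 0.00248; 304 ± 111 against 538 ± 133 CPM) and Ifi47 (-1.11 ± 0.18) led it.

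Of the 20 male-type STAT5 genes, 5 fell and 15 were not past the threshold (14 down with p adjusted over the list alone); median -0.77, camera adjusted p = 2.26e-21, adjusted p = 0.00465 with an estimated correlation. Per library, the level of the list differed by -1.06, exact permutation p = 1.59e-06 two-sided, adjusted p = 4.92e-05, higher in 0% of library pairs, with -1.19 in the first batch and -0.97 in the second. The steroid enzyme Hsd3b5 (-3.26 ± 0.73, adjusted p = 0.0344) had the largest decrease among well expressed genes, and Nudt7 (-1.29 ± 0.26), Igfals (-0.77 ± 0.17), which carries insulin-like growth factor in blood, and the pseudogene Serpina4-ps1 (-2.70 ± 0.53) also fell. The stress gene Chac1 (-1.52 ± 0.36, adjusted p = 0.0462) and the transcription factor gene Onecut1 (-1.70 ± 0.40, adjusted p = 0.0498) fell too. The genes that rose were led by the kinase gene Grk3 (0.92 ± 0.21, adjusted p = 0.0347), Sipa1l2 (0.88 ± 0.20) and the lipid enzyme Agpat1 (0.52 ± 0.10).

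Myc was at -0.06 ± 0.26, adjusted p = 0.93 between ruxolitinib and vehicle. The list of 40 proliferation genes, none past the threshold in edgeR, had median 0.83, camera adjusted p = 2.47e-12, adjusted p = 0.58 with an estimated correlation. Calls that depend on single libraries are those of Onecut1 (lost without any 1 of 22 of the 25 libraries), Chac1 (21), Sipa1l2 (19), Grk3 (14), Hsd3b5 (13) and Igfals (10), and of Cish without 1144. The count of 75 went to 48 without library 1145. A single fit of all 58 libraries called 320 genes, 159 up and 161 down, so the balance of directions depends on the model. In the first batch alone 907 genes changed, 798 of them up, and in the second batch alone 9. First-batch ruxolitinib libraries 860 and 861 stand apart, with the leukocyte gene Ptprc at 120.8 and 101.1 CPM against 13.75 to 25.83 in the vehicle libraries of that batch, and hepatocyte list levels of 8.707 and 8.602. The Kupffer cell list level differed by 1.95 in the first batch and -0.53 in the second. Without 860, 861, 864 and 865, 102 genes changed, 7 up and 95 down.

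The ruxolitinib effects in mApple and Myc livers share no libraries, and 13467 genes were tested in both. Of the 52 and 69 genes that fell, 29 fell in both, where 0.266 would be expected if the calls were unrelated (Fisher exact p = 1.27e-55). They include Ifit1, Ifit3, Rsad2, Rtp4, Irgm2, Mx2, Irf9, Parp14 and Stat2, all interferon genes, and the epidermal growth factor receptor gene Egfr (log2 fold change -1.18 with mApple and -1.03 with Myc). Ifit1 (-2.50 and -2.39) and Ifit3 (-1.88 in both) had nearly equal values. Of the genes called with mApple, 94.2% of those lower had the same sign with Myc, and no gene rose in both, with 1 and 6 called (113 at unadjusted p under 0.05). Across genes, which are not independent replicates, the Pearson r of the log2 fold changes was 0.444 and the Spearman rho 0.318. Egfr was chosen after its values were seen.

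**Figure D3:**
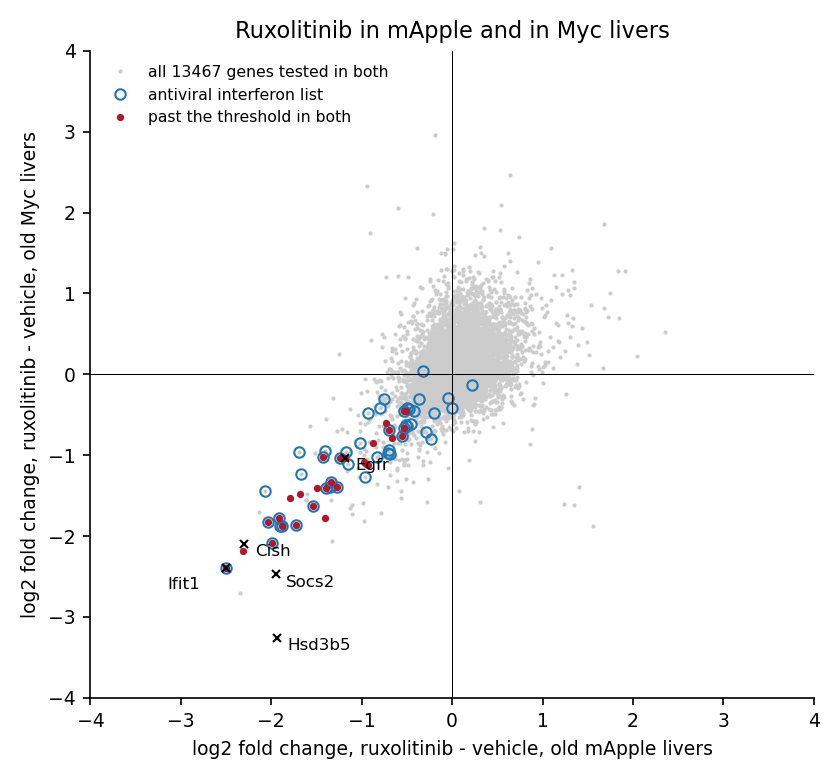
Log2 fold change with ruxolitinib in old mApple livers against that in old Myc livers for 13467 genes in grey. Blue circles are the type I interferon list, red dots are genes past the threshold in both, and crosses mark Socs2, Cish, Hsd3b5, Egfr and Ifit1.

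With edgeR no gene was called for a different response to ruxolitinib in mApple and Myc livers. The interaction called 0 of 14046 genes, with 735 at unadjusted p under 0.05, and DESeq2 called 2. Interaction values of interferon genes were 0.23 ± 0.59, adjusted p = 0.949 for Ifit1, 0.20 ± 0.56, adjusted p = 0.953 for Usp18 and 0.41 ± 0.54, adjusted p = 0.889 for Irf7. Myc was at 0.86 ± 0.43, adjusted p = 0.816. The interferon list had a median of 0.02 (camera adjusted p = 0.825). Its level per library had the opposite sign, -0.12, permutation p = 0.774, adjusted p = 0.964. That median crossed 0 with single libraries, from -0.17 without 1136 to 0.11 without 1140. Changes implanted in the counts at a log2 size of 1 were found for 73% of genes here, and at a size of 2 for 95%, so smaller differences between the livers would be missed.

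What Myc adds in aged livers was asked under vehicle and under ruxolitinib. The Myc vector in old livers under vehicle (n = 11 against 8 with mApple) came with higher genes for ribosome production, cell division and interferon response. Myc rose (1.70 ± 0.39, adjusted p = 0.0049). Npm1, a nucleolar protein needed to build ribosomes (0.97 ± 0.13, adjusted p = 7.93e-05), and the mitotic kinase gene Cdk1 (2.24 ± 0.38, adjusted p = 4.43e-04) rose, and Alb (-0.60 ± 0.13, adjusted p = 0.00269), the main secreted liver protein, fell. Of 13547 genes 2544 changed, 1459 up and 1085 down.

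In the list of 44 Myc targets for ribosome production and nucleotide synthesis, 36 rose and 8 were not past the threshold (39 up with p adjusted over the list alone); median 0.67, camera adjusted p = 8.03e-26, adjusted p = 0.353 with an estimated correlation. Examples are Mrto4 (0.74 ± 0.08) and Nle1 (1.24 ± 0.16) for the large ribosomal subunit and Impdh2 (0.88 ± 0.10) for guanine nucleotides. Of 40 proliferation genes, 37 rose and 3 were not past the threshold (39 up with p adjusted over the list alone); median 1.65, camera adjusted p = 9.31e-20, adjusted p = 0.492 with an estimated correlation. Cdca3 (2.25 ± 0.40), Ccna2 (1.54 ± 0.28) and Birc5 (1.45 ± 0.27) rose. Of 18 p53 and senescence genes, 6 rose and 12 were not past the threshold (10 up with p adjusted over the list alone); median 0.39, camera adjusted p = 7.42e-05, adjusted p = 0.492 with an estimated correlation. Its largest increase was Ckap2 (2.44 ± 0.49), a spindle protein, followed by the death receptor genes Eda2r (1.18 ± 0.33) and Tnfrsf10b (1.13 ± 0.30).

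Of 48 type I interferon genes, 29 rose and 19 were not past the threshold (41 up with p adjusted over the list alone); median 0.83, camera adjusted p = 3.74e-15, adjusted p = 0.608 with an estimated correlation. Isg15, a ubiquitin-like modifier (1.62 ± 0.41, adjusted p = 0.00883), Irf7 (1.19 ± 0.29, adjusted p = 0.00729), Bst2, which tethers virus particles (0.96 ± 0.18, adjusted p = 0.00103; 180 ± 58 against 90.3 ± 17.8 CPM), and Ifi27 (1.20 ± 0.23) rose, with Oasl2 (1.35 ± 0.37), Usp18 (1.31 ± 0.34), Ifit3 (1.05 ± 0.31), Ifi27l2a (1.29 ± 0.26) and Ifi35 (0.62 ± 0.11). Ifit1 (1.06 ± 0.42, adjusted p = 0.0831) was not past the threshold. As a mean of the list per library the difference was 0.79, exact permutation p = 0.00593 two-sided, adjusted p = 0.0318, higher in 97.7% of library pairs. In the interferon gamma list (26 genes), 8 rose and 18 were not past the threshold (9 up with p adjusted over the list alone), among them Gbp10 (1.54 ± 0.35) and Gbp3 (1.33 ± 0.32). Of immune cell markers, the T cell list had median -0.09, camera adjusted p = 0.467, that of natural killer cells median 0.10, camera adjusted p = 0.65, B and plasma cells median 0.16, camera adjusted p = 0.753, and monocytes and macrophages median 0.23, camera adjusted p = 0.182.

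Of 18 endothelial genes, 14 fell and 4 were not past the threshold (15 down with p adjusted over the list alone); median -0.44, camera adjusted p = 9.16e-09, adjusted p = 0.492 with an estimated correlation. Kdr, a receptor for vascular endothelial growth factor (-0.54 ± 0.11), Flt4 (-0.57 ± 0.11), Fcgr2b (-0.55 ± 0.10) and Dnase1l3 (-0.50 ± 0.10), all markers of the liver sinusoids, fell. Of 32 hepatocyte genes, 8 fell and 24 were not past the threshold (8 down with p adjusted over the list alone); median -0.19, camera adjusted p = 0.00201, adjusted p = 0.608 with an estimated correlation. They include Apoa1 (-0.57 ± 0.14) and the bile acid enzyme gene Cyp8b1 (-0.87 ± 0.21). In the male-type STAT5 list (20 genes), 4 fell and 16 were not past the threshold (4 down with p adjusted over the list alone); median -0.22, camera adjusted p = 0.113. Its level differed by -0.27, exact permutation p = 0.121 two-sided, adjusted p = 0.264, higher in 36.4% of library pairs, with -0.56 in the first batch and 0.05 in the second. Its members C6 (-0.81 ± 0.19) and Elovl3 (-1.13 ± 0.34) fell, as did the growth hormone receptor gene Ghr (-0.44 ± 0.08), and the female-type Cyp2b13 (2.45 ± 0.50) and Cyp2b9 (1.85 ± 0.53) rose. The fetal RNA H19 rose (1.83 ± 0.52) and Mycn fell (-1.41 ± 0.31). Large changes were the sulfotransferase gene Sult2a7 (3.32 ± 0.46, adjusted p = 8.21e-05) and Smpdl3b (2.77 ± 0.35, adjusted p = 4.03e-05) upward, and Srgap3 (-2.33 ± 0.28, adjusted p = 2.96e-05) and Adgrf1 (-2.23 ± 0.28, adjusted p = 3.46e-05) downward.

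The non-coding RNA genes Rmrp (3.45 ± 1.12, adjusted p = 0.0369), Rn45s (3.06 ± 0.98, adjusted p = 0.0338) and Rpph1 (2.94 ± 0.89, adjusted p = 0.0251) also rose, calls that are lost without any 1 of 8, 6 and 4 of the 19 libraries, and that of Elovl3 without 855 or 863. Library 858 alone has 11.3% of its counts in Rn45s, the ribosomal RNA precursor, and 2302 genes changed without it. Without library 870 the count was 3085, and the lowest was 1931, without 855.

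Under ruxolitinib, old livers with Myc (n = 14) were compared with mApple (n = 9) in the same way. Myc rose (2.54 ± 0.24, adjusted p = 1.25e-06), and so did Dkc1, which modifies ribosomal RNA (0.89 ± 0.10, adjusted p = 7.62e-06), and Cdk1 (2.12 ± 0.33, adjusted p = 2.33e-04). Irf7 (chromosome 7, 141263183 to 141266424) rose (1.85 ± 0.45, adjusted p = 0.00807). Of 14010 genes 2012 changed, 1177 up and 835 down.

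Of the 44 ribosome and nucleotide genes, 31 rose and 13 were not past the threshold (37 up with p adjusted over the list alone); median 0.60, camera adjusted p = 1.91e-25, adjusted p = 0.155 with an estimated correlation. The RNA helicase gene Ddx21 (0.82 ± 0.09) and Wdr43 (0.80 ± 0.10) are examples. Of 40 proliferation genes, 38 rose and 2 were not past the threshold (40 up with p adjusted over the list alone); median 2.01, camera adjusted p = 1.12e-32, adjusted p = 0.155 with an estimated correlation. The replication helicase gene Mcm6 (1.59 ± 0.24), Foxm1 (2.33 ± 0.37), Ccnb1 (3.02 ± 0.52) and Hmmr (2.98 ± 0.49) rose, together with Ckap2 (3.05 ± 0.47). Libraries 860 and 861, first-batch Myc, had the proliferation levels 4.684 and 4.115, Mki67 at 112.6 and 78.74 CPM and Ptprc at 120.8 and 101.1 CPM. In that batch the Kupffer cell list level differed by 1.51 and the monocyte and macrophage list level by 0.964, against 0.111 and 0.0399 in the second. Without 860, 861, 864 and 865, 2051 genes changed. The p53 target Zmat3 rose (0.87 ± 0.15).

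Of 48 type I interferon genes, 22 rose and 26 were not past the threshold (30 up with p adjusted over the list alone); median 0.78, camera adjusted p = 5.26e-12, adjusted p = 0.665 with an estimated correlation. Lgals3bp (1.01 ± 0.19, adjusted p = 0.00133), Oasl1 (1.13 ± 0.26), the RNA helicase gene Ddx60 (1.33 ± 0.33), Oasl2 (2.03 ± 0.63) and Usp18 (1.41 ± 0.47, adjusted p = 0.0451) rose, and Ifit1 did by a narrow margin (1.25 ± 0.42, adjusted p = 0.05). Isg15 (1.38 ± 0.47, adjusted p = 0.0512) and Ifit3 (1.08 ± 0.40, adjusted p = 0.0724) were not past it. The mean level of the list differed by 0.74, exact permutation p = 0.00502 two-sided, adjusted p = 0.0311, higher in 87.9% of library pairs, 0.45 in the first batch and 0.91 in the second. The calls of Ifit1, Usp18 and Oasl2 are lost without any 1 of 14, 13 and 6 of the 23 libraries. The interferon gamma list had median 0.43, camera adjusted p = 0.0145, adjusted p = 0.973 with an estimated correlation.

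Of 20 male-type STAT5 genes, 5 fell and 15 were not past the threshold (7 down with p adjusted over the list alone); median -0.40, camera adjusted p = 9.49e-04, adjusted p = 0.665 with an estimated correlation. Hsd3b5 (-3.15 ± 0.82, adjusted p = 0.0123), Elovl3 (-2.76 ± 0.43, adjusted p = 2.33e-04), the organic anion transporter gene Slco1a1 (-2.08 ± 0.55) and C6 (-1.11 ± 0.19) fell, Socs2 fell (-1.0 ± 0.33, adjusted p = 0.0456; lost without any 1 of 15 libraries), and Cyp2b9 rose (2.08 ± 0.59). Of 18 endothelial genes, 6 fell and 12 were not past the threshold (11 down with p adjusted over the list alone); median -0.44, camera adjusted p = 7.77e-06, adjusted p = 0.665 with an estimated correlation. Tek (-0.64 ± 0.16), the receptor for angiopoietin, Tie1 (-0.38 ± 0.11; not without 1142, 1143 or 860) and Kdr (-0.62 ± 0.18; not without any 1 of 4 libraries) fell. Sult2a7 (3.92 ± 0.79), Smpdl3b (3.25 ± 0.28), H19 (1.53 ± 0.38) and the lipase gene Lpl (1.43 ± 0.39), here a marker of lipid-laden macrophages, rose. Srgap3 (-2.04 ± 0.49), Adgrf1 (-2.0 ± 0.27), Mycn (-1.96 ± 0.29) and Apoa1 (-0.53 ± 0.14) fell. With and without ruxolitinib, 765 of 1459 (vehicle) and 1152 (ruxolitinib) genes rose in both comparisons where 124 would be expected, and 323 of 1082 and 817 fell in both where 65.3 would be, over 13529 genes and without shared libraries (across genes, Pearson r = 0.707, rho = 0.594). The first batch alone, with 4 libraries on each side, called 0 genes.

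**Figure D4:**
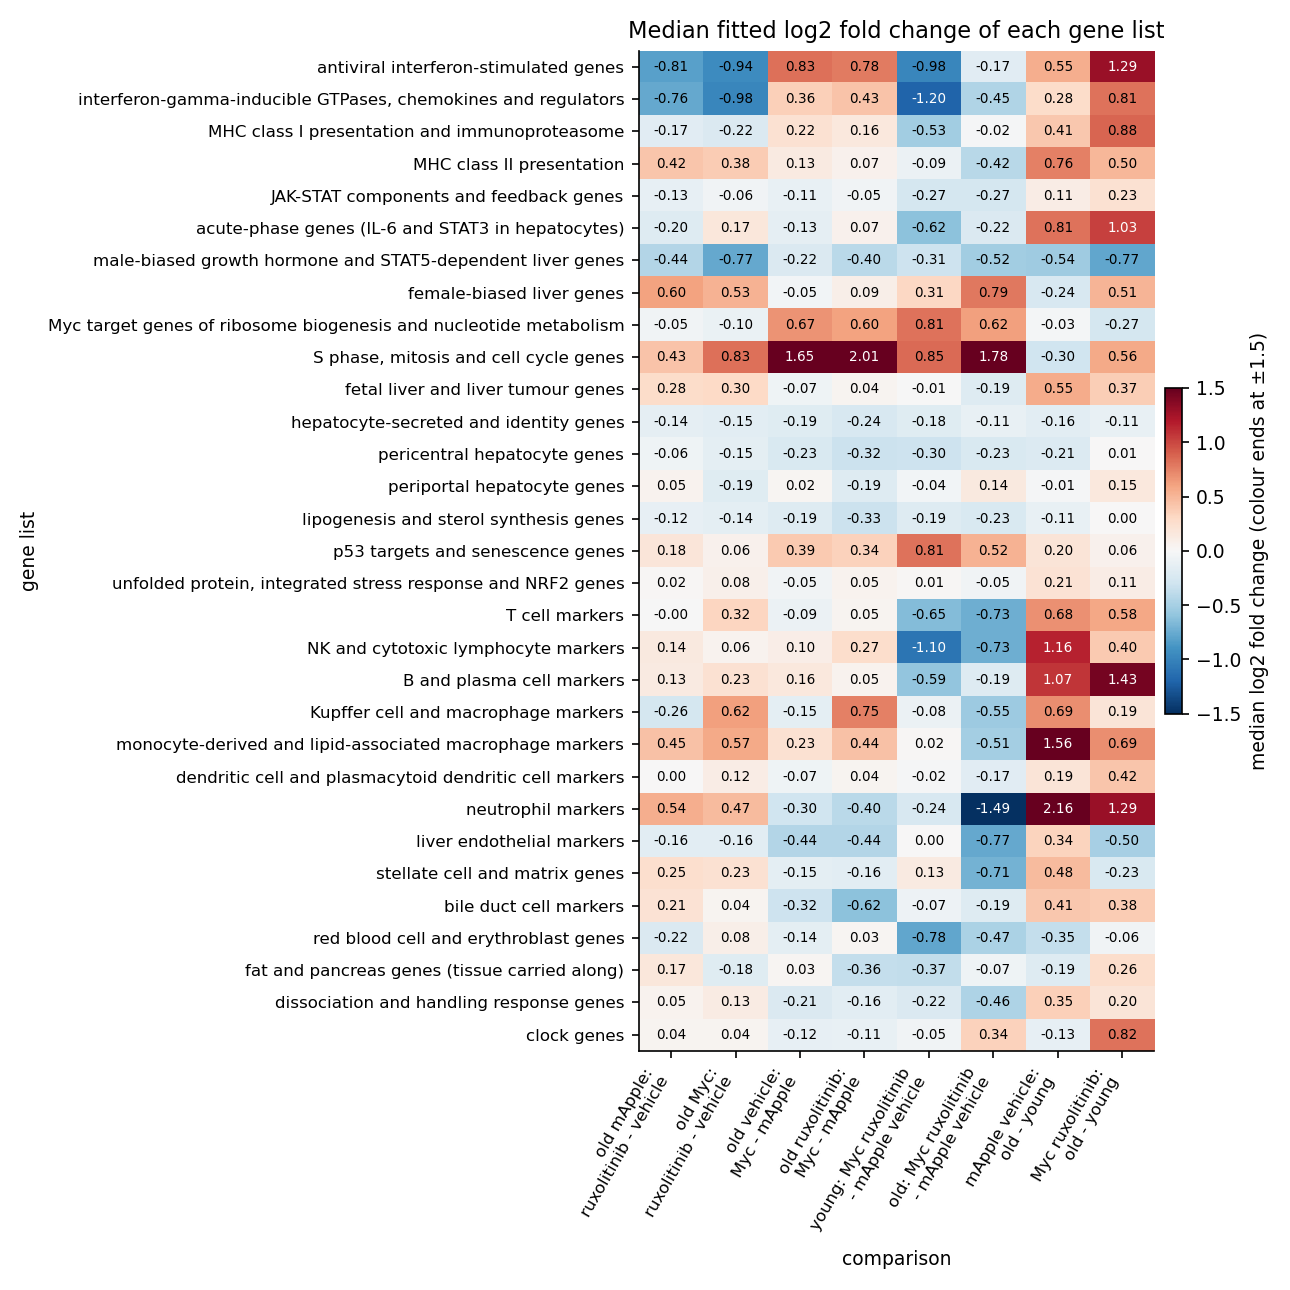
Median log2 fold change of each of 31 gene lists in 8 comparisons. Colours end at -1.5 and 1.5, and the interferon list stands at -0.81 and -0.94 with ruxolitinib in old livers and at 1.29 in old against young Myc livers.

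Age was compared first without Myc or drug. Old and young mApple vehicle livers of the second batch (n = 4 and 6) differed in genes that include markers of immune cells. Cx3cr1 (1.94 ± 0.27, adjusted p = 0.00889) and Ccr2 (1.79 ± 0.29, adjusted p = 0.016), chemokine receptors of monocytes, were higher in old livers. S100a8 (2.67 ± 0.46, adjusted p = 0.0204), abundant in neutrophils, and Jchain, which joins antibody units in plasma cells (2.79 ± 0.33, adjusted p = 0.00534), rose too, S100a8 not without any 1 of 5 libraries and Ccr2 not without 1135. Cyp4a12a, a fatty acid hydroxylase of the male liver, fell (-1.44 ± 0.21, adjusted p = 0.0107). Of 13155 genes 145 changed, 113 up and 32 down, while a single fit of all 58 libraries, which adds first-batch old livers, gave 200, 78 up and 122 down.

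Of 19 monocyte and macrophage genes, 6 rose and 13 were not past the threshold (18 up with p adjusted over the list alone); median 1.56, camera adjusted p = 1.97e-15, adjusted p = 0.119 with an estimated correlation. Gpnmb (3.87 ± 0.65, adjusted p = 0.0172) and Cd63 (1.37 ± 0.25) were among them, and the list level differed by 0.98, higher in 100% of pairs. Of 13 neutrophil genes only 4 passed the filter on low counts, which a gene high in old livers alone can pass. Of these 4, 3 rose and 1 was not past the threshold (4 up with p adjusted over the list alone), with median 2.16, camera adjusted p = 1.36e-05, adjusted p = 0.119 with an estimated correlation. The list level, which needs no such filter, differed by 0.587, higher in 100% of pairs. The hepatocyte list level differed by -0.276, higher in 0%. These 3 levels each had exact permutation p = 0.00476, adjusted p = 0.0492. S100a9 (2.26 ± 0.41) and the receptor gene Csf3r (1.54 ± 0.30) rose with the interleukin 1 antagonist gene Il1rn (1.59 ± 0.31) and the antigen-presenting H2-Q4 (0.65 ± 0.12). Lcn2, an iron-binding defence protein, sits at the threshold (4.43 ± 0.95, adjusted p = 0.0498; 108 ± 181 against 5.03 ± 4.34 CPM) and its call is lost without any 1 of 8 libraries. So are those of Il1rn and Ntrk2 (8 each), H2-Q4 (7), Cd63 and Csf3r (6 each) and S100a9 (4), and that of Gpnmb without 1130 or 1131. Noct (3.62 ± 0.54), a clock-linked phosphatase, and the receptor gene Ntrk2 (2.91 ± 0.62) also rose.

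Of 20 male-type STAT5 genes, 4 fell and 16 were not past the threshold (9 down with p adjusted over the list alone); median -0.54, camera adjusted p = 1.08e-08, adjusted p = 0.119 with an estimated correlation. Cyp4a12b (-1.36 ± 0.19) and Slco1a1 (-1.34 ± 0.27) fell, as did Acot1 (-1.58 ± 0.22), Nat8f5 (-1.47 ± 0.32) and the tryptophan enzyme gene Tdo2 (-0.57 ± 0.12). The calls of Slco1a1 (9 libraries), Nat8f5 (8) and Tdo2 (8) are lost without any 1 of these, and those of Cyp4a12a and Cyp4a12b without 1135. Of 47 type I interferon genes 0 passed with edgeR (3 up with p adjusted over the list alone, 16 at unadjusted p under 0.05), and DESeq2 and limma voom called 4 each; median 0.55, camera adjusted p = 7.84e-04, adjusted p = 0.624 with an estimated correlation. Irf7 was at 1.20 ± 0.31, adjusted p = 0.082, Usp18 at 1.07 ± 0.46, adjusted p = 0.244, Ifit1 at 0.90 ± 0.57, adjusted p = 0.428, Isg15 at 0.92 ± 0.49, adjusted p = 0.344 and Myc at -0.43 ± 0.51, adjusted p = 0.691. The list level differed by 0.31, exact permutation p = 0.329 two-sided, adjusted p = 0.509, higher in 54.2% of library pairs, and its median was -0.08 without library 1136. The count of 145 was 22 without 1135, 40 without 1131, 53 without 1133, 54 without 1130, 67 without 1132, 71 without 1136, 77 without 1138 and 502 without 1129. Library 1134, young mApple vehicle, has the lowest share of its reads in exons, 63.8%.

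The effect of age was also measured where Myc and drug are both present. Among livers given both Myc and ruxolitinib, interferon genes were much higher in old (n = 10) than in young mice (n = 10). Irf7, a driver of interferon production, rose (3.14 ± 0.38, adjusted p = 4.22e-06; 123 ± 76.2 against 14.2 ± 4.2 CPM), and so did Usp18 (2.60 ± 0.27, adjusted p = 8.91e-07) and Oasl2 (3.23 ± 0.56, adjusted p = 2.01e-04). H2-D1, a class I molecule that presents peptides to T cells, rose with little spread (1.15 ± 0.08, adjusted p = 4.03e-09; 749 ± 72.9 against 344 ± 46 CPM). Myc itself was lower in old livers (-0.69 ± 0.10, adjusted p = 3.33e-05; 31.3 ± 6.14 against 51.5 ± 7.32 CPM). Of 12760 genes 4306 changed, 2314 up and 1992 down.

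Of 46 type I interferon genes, 39 rose and 7 were not past the threshold (41 up with p adjusted over the list alone); median 1.29, camera adjusted p = 2.31e-16, adjusted p = 0.361 with an estimated correlation. Ifi44 (3.93 ± 0.57), Oas1g (3.52 ± 0.51), Isg15 (2.40 ± 0.43, adjusted p = 2.52e-04), Ifit1 (1.88 ± 0.36), Ifit3 (1.65 ± 0.35) and Mx2 (1.86 ± 0.15) rose. Per library, the level of the list differed by 1.05, exact permutation p = 2.06e-04 two-sided, adjusted p = 7.38e-04, higher in 94% of library pairs. In the interferon gamma list (25 genes), 20 rose and 5 were not past the threshold (22 up with p adjusted over the list alone); median 0.81, camera adjusted p = 2.50e-08, adjusted p = 0.361 with an estimated correlation. Of 20 class I antigen presentation genes, 19 rose and 1 was not past the threshold (19 up with p adjusted over the list alone); median 0.88, camera adjusted p = 1.46e-20, adjusted p = 0.0725 with an estimated correlation. H2-T23 (1.21 ± 0.10) and H2-Q4 (1.31 ± 0.11) are among them, and the list level differed by 0.80, exact permutation p = 1.08e-05 two-sided, adjusted p = 1.68e-04, higher in 100% of library pairs. H2 genes are close paralogs, so reads may be shared among them.

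Of 32 acute phase genes, 24 rose and 8 were not past the threshold (28 up with p adjusted over the list alone); median 1.03, camera adjusted p = 8.66e-08, adjusted p = 0.475 with an estimated correlation. Apcs (2.23 ± 0.39), the haem carrier gene Hpx (1.16 ± 0.19) and Socs3 (2.11 ± 0.31), a feedback inhibitor of interleukin 6 signalling, rose, and Lcn2 had the largest increase among well expressed genes (5.06 ± 1.13, adjusted p = 0.0018). The acute phase list level was 8.908, 8.803, 9.061 and 8.532 in old libraries 1149, 1150, 1154 and 1158. The other old libraries had 6.884 to 7.239, within the young range of 6.291 to 7.884. Interferon list levels were 3.159, 2.957 and 3.266 in 1149, 1154 and 1158 and 4.16 in 1150, against 2.695 to 3.284 in young livers. Of 17 monocyte and macrophage genes, 12 rose and 5 were not past the threshold (16 up with p adjusted over the list alone); median 0.69, camera adjusted p = 5.89e-05, adjusted p = 0.361 with an estimated correlation. Gpnmb (2.37 ± 0.42) and Trem2 (1.19 ± 0.19) rose. Of the 20 B cell and plasma cell genes only 5 passed the filter on low counts, and all 5 rose, Jchain at 2.89 ± 0.38. A gene high in old livers alone can pass that filter, so the 5 do not stand for the list. Of 20 male-type STAT5 genes, 2 rose, 14 fell and 4 were not past the threshold (2 up and 16 down with p adjusted over the list alone); median -0.77, camera adjusted p = 9.31e-08, adjusted p = 0.122 with an estimated correlation. Hsd3b5 (-3.98 ± 0.61, adjusted p = 5.55e-05), Elovl3 (-2.78 ± 0.36) and Slco1a1 (-2.62 ± 0.42) fell, while the female-type Cyp2b9 (3.75 ± 0.51) and Cyp2b13 (3.66 ± 0.45) rose.

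Of the 44 ribosome and nucleotide genes, 27 fell and 17 were not past the threshold (30 down with p adjusted over the list alone); median -0.27, camera adjusted p = 1.61e-09, adjusted p = 0.361 with an estimated correlation. Cad (-0.92 ± 0.11), the first enzyme of pyrimidine synthesis, Srm (-0.88 ± 0.14) and Nolc1 (-0.66 ± 0.13) fell together with Myc. Of 18 endothelial genes, 11 fell and 7 were not past the threshold (14 down with p adjusted over the list alone); median -0.50, camera adjusted p = 1.22e-05, adjusted p = 0.504 with an estimated correlation. Kdr (-0.81 ± 0.19), Tek (-0.79 ± 0.18) and Stab1 (-0.49 ± 0.13) fell. H19 rose (2.09 ± 0.35); the transcription factor gene Pitx3 (-4.01 ± 0.31), Ces2b (-2.85 ± 0.42) and Clic3 (-2.76 ± 0.30) fell by large amounts, and the Kupffer cell gene Cd163 fell (-1.40 ± 0.40). The clock genes Dbp (3.33 ± 0.35), which rose, and Cry1 (-1.51 ± 0.16), which fell, changed as well, and labels give no time of day. The old libraries of this comparison are deeper, with a median of 22.4 M exon counts against 12.7 M.

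In young mice, livers with Myc and ruxolitinib (n = 10) against mApple and vehicle (n = 6) differ in vector and drug at the same time, so neither can be assigned a change. Myc rose (2.27 ± 0.28, adjusted p = 6.98e-06; 51.5 ± 7.32 against 10.6 ± 7.35 CPM), and the polyamine enzyme gene Srm, a direct Myc target, rose with it (1.62 ± 0.09, adjusted p = 2.29e-09). Interferon and STAT5 targets fell, such as Irf9 (-1.53 ± 0.09, adjusted p = 2.29e-09) and Socs2 (-4.08 ± 0.40, adjusted p = 5.29e-07; 1.72 ± 0.615 against 29.4 ± 25.1 CPM). Of 12808 genes 3524 changed, 1725 up and 1799 down.

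Of 47 type I interferon genes, 1 rose, 39 fell and 7 were not past the threshold (1 up and 41 down with p adjusted over the list alone); median -0.98, camera adjusted p = 4.22e-23, adjusted p = 0.0403 with an estimated correlation. Past the threshold, the interferon genes Ifit1 (-1.84 ± 0.18, adjusted p = 5.29e-07), Ifit3 (-1.51 ± 0.15), Oasl2 (-1.61 ± 0.20), Usp18 (-1.56 ± 0.17), Isg15 (-1.04 ± 0.23) and Irf7 (-0.99 ± 0.16) fell. As a mean of the list per library the difference was -0.75, exact permutation p = 1.25e-04 two-sided, adjusted p = 7.74e-04, higher in 0% of library pairs. The T cell and natural killer cell list levels were lower too, with differences of -0.13, exact permutation p = 0.00112 two-sided, adjusted p = 0.00387, higher in 5% of library pairs, and -0.19, exact permutation p = 5.0e-04 two-sided, adjusted p = 0.00221, higher in 3.33% of library pairs. Of 25 interferon gamma genes, 22 fell and 3 were not past the threshold (23 down with p adjusted over the list alone); median -1.20, camera adjusted p = 2.98e-13, adjusted p = 0.14 with an estimated correlation. Irgm2 (-1.97 ± 0.15) and Gbp11 (-2.90 ± 0.38) fell. Of 20 class I presentation genes, 18 fell and 2 were not past the threshold (19 down with p adjusted over the list alone); median -0.53, camera adjusted p = 1.01e-08, adjusted p = 0.154 with an estimated correlation. H2-Q7 (-0.81 ± 0.11) and the peptide transporter gene Tap1 (-0.66 ± 0.10) fell, with Stat2 (-0.77 ± 0.08) and Stat3 (-0.71 ± 0.10).

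Of the 44 ribosome and nucleotide genes, 40 rose and 4 were not past the threshold (42 up with p adjusted over the list alone); median 0.81, camera adjusted p = 7.86e-34, adjusted p = 0.0255 with an estimated correlation. Impdh2 (1.02 ± 0.07) and Polr1b (1.0 ± 0.07), a subunit of the polymerase for ribosomal RNA, rose. Of 18 p53 genes, 12 rose and 6 were not past the threshold (16 up with p adjusted over the list alone); median 0.81, camera adjusted p = 3.01e-09, adjusted p = 0.0403 with an estimated correlation. Eda2r (3.35 ± 0.25), Tnfrsf10b (2.15 ± 0.26) and Zmat3 (1.10 ± 0.09) rose. Of 38 proliferation genes, 9 rose, 1 fell and 28 were not past the threshold (9 up and 1 down with p adjusted over the list alone); median 0.85, camera adjusted p = 5.54e-08, adjusted p = 0.469 with an estimated correlation. The mApple library 1129 stands apart on this list, at 3.004 against 1.329 to 1.576 in the other 5, with Mki67 at 20.22 CPM against 0.8346 to 3.258. Mcm6 rose (1.56 ± 0.33) and E2f8, which limits replication in hepatocytes, fell (-0.96 ± 0.21). Of 32 acute phase genes, 1 rose, 17 fell and 14 were not past the threshold (2 up and 19 down with p adjusted over the list alone); median -0.62, camera adjusted p = 2.15e-07, adjusted p = 0.367 with an estimated correlation, with Apcs (-1.64 ± 0.19) and Socs3 (-2.06 ± 0.30) lower. Cyp2b10 (3.42 ± 0.34), Cyp3a59 (2.55 ± 0.16), Sult2a7 (4.54 ± 0.39) and Smpdl3b (3.84 ± 0.26) had some of the largest increases, and Cish (-3.65 ± 0.60), Srgap3 (-3.49 ± 0.30) and Onecut1 (-3.29 ± 0.46) of the largest decreases. Alb fell (-0.85 ± 0.14), and the early response gene Egr1 fell (-1.76 ± 0.32).

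The same contrast was made in old mice of the second batch (n = 10 and 4). Myc rose (2.01 ± 0.29, adjusted p = 0.00126), as did Npm1 (0.87 ± 0.12, adjusted p = 0.00121) and Cdk1 (2.51 ± 0.50, adjusted p = 0.0075). Socs2 fell (-3.14 ± 0.38, adjusted p = 3.36e-04), and so did Il6st (-0.92 ± 0.10, adjusted p = 2.55e-04). Of 13761 genes 1496 changed, 897 up and 599 down.

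Of 48 type I interferon genes 0 passed the threshold with edgeR (4 down at unadjusted p under 0.05), 0 with DESeq2 and 3 with limma voom (median -0.17, camera adjusted p = 0.387). A single fit of all 58 libraries called 5 up and 8 down (median -0.128, camera adjusted p = 0.0397). Ifit1 was at -0.86 ± 0.63, adjusted p = 0.39, Irf7 at 0.95 ± 0.59, adjusted p = 0.314 and Usp18 at -0.03 ± 0.49, adjusted p = 0.974. The mean level of the list differed by -0.01, exact permutation p = 0.977 two-sided, adjusted p = 0.977, higher in 50% of library pairs. Single libraries moved the median: -0.31 without 1135, 0.40 without 1136, -0.27 without 1138, -0.10 without 1149 or 1158, and -0.07 without 1154. Of 25 JAK-STAT genes, 6 fell and 19 were not past the threshold (7 down with p adjusted over the list alone); median -0.27, camera adjusted p = 1.60e-04, adjusted p = 0.0182 with an estimated correlation. The receptor kinase genes Jak1 (-0.38 ± 0.10) and Jak2 (-0.39 ± 0.09) and Stat3 (-0.60 ± 0.16) fell, calls that are lost for Jak1 without 1136 or 1137, Jak2 without 1137 and Stat3 without 1135, 1136 or 1137.

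Of the 44 ribosome and nucleotide genes, 28 rose and 16 were not past the threshold (34 up with p adjusted over the list alone); median 0.62, camera adjusted p = 1.43e-18, adjusted p = 0.183 with an estimated correlation. Nle1 (1.36 ± 0.18) and Hspe1 (0.64 ± 0.08) rose. Of 40 proliferation genes, 26 rose and 14 were not past the threshold (34 up with p adjusted over the list alone); median 1.78, camera adjusted p = 7.05e-18, adjusted p = 0.331 with an estimated correlation. Rrm2 (1.59 ± 0.35), which supplies DNA precursors, and Ckap2 (3.28 ± 0.82) rose. Of 18 p53 genes, 10 rose and 8 were not past the threshold (11 up with p adjusted over the list alone); median 0.52, camera adjusted p = 7.41e-09, adjusted p = 0.0525 with an estimated correlation. Eda2r (2.08 ± 0.39), Psrc1 (2.59 ± 0.46), Phlda3 (1.41 ± 0.27) and Zmat3 (0.90 ± 0.11) rose. Of 18 endothelial genes, 13 fell and 5 were not past the threshold (15 down with p adjusted over the list alone); median -0.77, camera adjusted p = 2.93e-09, adjusted p = 0.361 with an estimated correlation. Tek (-1.11 ± 0.24), Kdr (-1.05 ± 0.25), Cdh5 (-0.99 ± 0.24) and Bmp2 (-1.07 ± 0.24) fell.

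Of 20 male-type STAT5 genes, 7 fell and 13 were not past the threshold (10 down with p adjusted over the list alone); median -0.52, camera adjusted p = 1.05e-04, adjusted p = 0.218 with an estimated correlation. Hsd3b5 (-3.61 ± 0.86, adjusted p = 0.0175) and Serpina4-ps1 (-3.17 ± 0.72) fell, and Cyp2b13 (3.80 ± 0.80), Hao2 (3.72 ± 0.96), Cyp2b9 (3.0 ± 0.80), Cyp2b10 (3.21 ± 0.85), Sult2a7 (4.04 ± 0.64) and H19 (1.92 ± 0.46) rose. The count of 1496 was 539 without library 1135, 838 without 1136 and 950 without 1137, all old mApple vehicle. Without 1135 or 1136 the calls of Kdr, Cdh5, Ckap2, Cyp2b9, Cyp2b10 and Hao2 are lost, without 1138 those of Ckap2, Cyp2b9 and Cyp2b10, without 1137 that of Hao2, without 1135 those of H19 and Hsd3b5, and without 1136 that of Serpina4-ps1.

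Whether the joint effect of vector and drug differs between old and young was tested as an interaction, with positive values for a higher response in old livers. Irf9 (1.14 ± 0.26, adjusted p = 0.0495) and class I genes H2-T10 (0.97 ± 0.17, adjusted p = 0.0153), H2-T22 (0.73 ± 0.16) and H2-K1 (0.61 ± 0.14) were higher. Il6st (-0.65 ± 0.14, adjusted p = 0.0359) and Kdr (-1.33 ± 0.30, adjusted p = 0.0491) were lower, as were B3gnt3 (-1.73 ± 0.32), Pitx3 (-2.49 ± 0.57), Akap12 (-1.92 ± 0.42), Itpkb (-1.83 ± 0.41) and the endothelial cadherin gene Pcdh12 (-1.56 ± 0.33). The intestinal fat carrier gene Fabp2 (0.94 ± 0.16) and Gstp3 (0.92 ± 0.21) were higher. Of 13609 genes 39 passed, 14 up and 25 down.

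Of 47 type I interferon genes, 1 rose and 46 were not past the threshold (14 up with p adjusted over the list alone); median 0.90, camera adjusted p = 9.09e-14, adjusted p = 0.572 with an estimated correlation. Irf7 was at 1.93 ± 0.59, adjusted p = 0.13, Oasl2 at 2.47 ± 0.86, adjusted p = 0.186 and Usp18 at 1.52 ± 0.53, adjusted p = 0.187, and the list level differed by 0.74, permutation p = 0.0787 two-sided, adjusted p = 0.349. Without library 1136 the median was 1.37. Of 20 class I genes, 2 rose and 18 were not past the threshold (12 up with p adjusted over the list alone); median 0.50, camera adjusted p = 2.32e-12, adjusted p = 0.285 with an estimated correlation. In the endothelial list (18 genes), 1 fell and 17 were not past the threshold (15 down with p adjusted over the list alone); median -0.82, camera adjusted p = 9.09e-14, adjusted p = 0.398 with an estimated correlation. Their level differed by -0.78, permutation p = 1.30e-04, adjusted p = 0.00403. Calls lost without any 1 of several of the 30 libraries are those of Gstp3 (24), Irf9 (23), Pitx3 (23), Kdr (20), H2-K1 (18), Itpkb (17), Akap12 (16), H2-T22 (13), Pcdh12 (11) and Il6st (10), and H2-T10 is lost without 1135 and B3gnt3 without 1135 or 1136. The gene count was 3 without library 1135, 7 without 1133, 8 without 1119, 1125 or 1128, 9 without 1131, 10 without 1130 and 13 without 1136. It was 16 without 1121, 17 without 1151, 19 without 1120, 20 without 1122, 22 without 1157, 23 without 1126, 25 without 1153 or 1158, 64 without 1154 and 78 without 1138.

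The 145 genes that differ with age in mApple vehicle livers were then followed under ruxolitinib. In the first batch of mApple livers, which shares no library with the age comparison, 20 of 142 such genes (14.1%) had a value opposite to their age difference, and edgeR called none of the 142 under the drug. Among genes not past the age threshold the share there was 35.4%. Across the 142 genes the values with age and with drug had Pearson r = 0.584, beside 0.45 for the genes not past the age threshold, and 0.457 and 0.259 without libraries 864 and 865. With both batches the share was 35.2%, and in the second batch, which shares its vehicle libraries with the age comparison, 84.1%, beside 44.5% and 61.1% of the genes not past the age threshold. In Myc livers, which share no library, it was 22.1% with both batches, 19.4% in the first and 68.3% in the second, beside 44.7%, 41.3% and 59.0% of the other genes. The interferon lists hold 0 of the age genes.

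Within each Myc group, Myc was compared with list levels after removing batch means, as a family of 12 correlations. Under vehicle in old livers (n = 11), Myc and the proliferation list had r = 0.877 (permutation p = 0.00224, adjusted p = 0.0161; rho = 0.727, permutation p = 0.0144). Without the 2 libraries farthest from the median r was 0.61 (permutation p = 0.0883), so the relation rests on those samples, and in the 6 libraries of the first batch it was 0.947 (exact permutation p = 0.0278; rho = 0.6, p = 0.242) and -0.32 without the farthest 2 (p = 0.792), with library 870 among the 6; the second batch holds 5, too few. For the same list r had the opposite sign under ruxolitinib, -0.566 in old livers (permutation p = 0.0353, adjusted p = 0.0847; rho = -0.442, p = 0.114) and -0.509 in young livers (permutation p = 0.13, adjusted p = 0.223; rho = -0.491, p = 0.158). Under ruxolitinib in old livers (n = 14), Myc and the list of ribosome and nucleotide genes had r = 0.647 (permutation p = 0.0119, adjusted p = 0.0476; rho = 0.565, permutation p = 0.0381), with 0.398 without the farthest 2 (permutation p = 0.204) and 0.394 in the second batch (permutation p = 0.264). In the same group Myc and the tumour and fetal list, which holds H19 and Mycn, had r = -0.738 (permutation p = 0.00268, adjusted p = 0.0161; rho = -0.596, permutation p = 0.0284), with -0.409 without the farthest 2 (permutation p = 0.189) and -0.382 in the second batch (permutation p = 0.276). Both relations rest on those samples, and the first batch, with 4 libraries, was not tested alone. For Myc and the interferon list r was 0.374 (rho = 0.336) under vehicle and -0.333 (rho = -0.0813) under ruxolitinib in old livers (adjusted permutation p = 0.293 for both), and -0.44 (rho = -0.515) in young livers (adjusted permutation p = 0.275).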

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

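Groups of 4 to 10 libraries were searched for single extreme values with Dixon's test, and the effects of old and young livers were compared by an interaction; no test in this part was chosen after results were seen. Dixon's test marks about 1 in 20 groups by chance, and it marked 11 of the 60 groups tested over 15 measures.

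In young Myc livers under ruxolitinib, library 1123 had a Myc level of 5.23 (nearest 5.59), below its group, and library 1124 had 11.2 M exon counts (nearest 12.2) and a ribosome and nucleotide list level of 5.32 (nearest 5.46). Library 1127 of the same group had the highest interferon list level, 3.28 (nearest 3.0), and the highest acute phase level, 7.88 (nearest 6.95). In young mApple vehicle livers, library 1134 had 63.8% of its reads in exons (nearest 81.2%), with low class I presentation (5.41, nearest 5.78) and ribosome and nucleotide levels (4.43, nearest 4.74). Library 1129 of that group had a proliferation level of 3.0 (nearest 1.58). Acute phase levels were high in library 1137, old mApple vehicle (9.14, nearest 7.71), and in library 864, old mApple ruxolitinib (10.3, nearest 7.35).

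Values also differed between ages. The change that comes with Myc and ruxolitinib together differed between old and young livers for 39 genes, and for the endothelial list level by -0.776 (adjusted permutation p = 0.00403). The 39 genes rest on few libraries, since only 3 were called without library 1135. No explanation was tested for these differences.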

How the results depend on the processing

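Runs without libraries 870, 858, 864 and 865 or 860, 861, 864 and 865, the split of vehicle libraries and the estimated correlation over all lists were chosen only after results were seen. No paired analysis was possible because library numbers are not shared between groups.

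The interferon list kept its sign in most settings, while its size moved: -0.61 in the first batch and -1.27 in the second for ruxolitinib in old mApple livers, 1.23 with voom for Myc under ruxolitinib and 0.171 with voom for age in mApple vehicle livers. Camera with an estimated correlation called it for the joint contrast in young livers (-0.978, adjusted p = 0.0403) and ended these calls: for ruxolitinib in old mApple livers -0.814 (adjusted p = 0.16) and in old Myc livers -0.939 (0.0823), for Myc under vehicle 0.831 (0.608) and under ruxolitinib 0.779 (0.665), for age in mApple vehicle livers 0.548 (0.624) and in Myc ruxolitinib livers 1.29 (0.361), and for the joint interaction 0.899 (0.572). Over all lists 5 tests passed that way, against 118.

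Counts of changed genes moved more, and the cause was not tested. For ruxolitinib in old mApple livers (53) they were 141 with DESeq2, 26 without a batch term, 6 in the first batch and 11 in the second. In old Myc livers (75) they were 177 with DESeq2, 320 in a single fit of all 58 libraries (159 up and 161 down, against 6 and 69), 44 without a batch term, 907 in the first batch and 9 in the second. Myc under vehicle (2544) gave 1468 without a batch term, 732 in the first batch and 629 in the second. Myc under ruxolitinib (2012) gave 1033 without a batch term and 0 in the first batch alone. Age in mApple vehicle livers (145) gave 666 with DESeq2 and 1640 with limma voom. The joint contrast in old livers (1496) gave 2832 with voom and 3349 in the single fit. The joint interaction (39) gave 198 with DESeq2 and 597 with voom, and the interaction of vector and drug (0) gave 2 with DESeq2. At unadjusted p under 0.05, 233 genes were lower with ruxolitinib in both kinds of liver, against 29.

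The share of changed genes that rose moved by over 10 points in some settings. For ruxolitinib in old mApple livers (1.89%) it was 20.6% with DESeq2 and 14.1% with voom or the single fit. In old Myc livers (8.0%) it was 30.0% without a filter, 32.2% with DESeq2, 49.7% in the single fit, 88.0% in the first batch and 22.2% in the second. For Myc under vehicle (57.4%) it was 70.4% in the single fit, 73.6% in the first batch and 70.7% in the second. For age in mApple vehicle livers (77.9%) it was 39.0% in the single fit, and for the joint interaction (35.9%) 58.1% in the single fit and 51.9% without a filter.

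Near 0 the interferon median changed sign. For the interaction of vector and drug (0.0228) it was -0.223 in the first batch, -0.0325 without 870, -0.018 without 858 and -0.0547 without 860, 861, 864 and 865. For the joint contrast in old livers (-0.171) it was 0.165 with voom, and in the single fit -0.128, where 5 genes were up and 8 down (adjusted p = 0.0397).

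Leaving out single libraries, the lowest and highest counts were 20 and 75 for ruxolitinib in mApple livers, 48 and 83 in Myc livers, 22 and 502 for age in mApple vehicle livers, 539 and 1662 for the joint contrast in old livers and 3 and 78 for the joint interaction. The interferon median ran from -0.168 to 0.113 for the interaction of vector and drug, from -0.0818 to 0.73 for age in mApple vehicle livers and from -0.314 to 0.401 for the joint contrast in old livers.

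The Myc difference under vehicle was 1.12 in the first batch (exact permutation p = 0.214). Correlations with Myc weakened: under vehicle, proliferation to 0.61 without the farthest 2 libraries; under ruxolitinib in old livers, the ribosome list to 0.398 without the farthest 2 and 0.394 in the second batch, the tumour and fetal list to -0.409 and -0.382, and proliferation (-0.566) to -0.442 (Spearman), -0.433 and -0.405. In young livers the tumour and fetal list went to -0.624 (Spearman) and -0.335 without the farthest 2.

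The share of age genes opposite to age under ruxolitinib (14.1% in the first batch of mApple livers) was 35.2% with both batches, 84.1% in the second, 22.1% with both batches and 68.3% in the second for Myc livers, 32.2% without 864 and 865, and 64.1% as the median over split vehicle libraries.

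Of 495 named gene results past the threshold, 196 were kept in every setting, 262 lost the call in at least 1 alternative, 150 without at least 1 library, and 7 changed sign; the cause was not tested. With Myc under ruxolitinib, in the first batch alone, Srgap3 was 0.368 and Usp18 -0.0641. In the single fit, the joint contrast in old livers gave Hmox1 0.308, Ier3 0.0954, Itgam 1.7, Mmp9 1.61 and Mrc1 0.132. The neutrophil gene Ngp, not past the threshold with Myc under ruxolitinib, ran from -2.57 to 2.98 as single libraries were left out.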

Other observations

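The tests of interferon genes in old against young Myc livers were chosen only after results were seen, while those of the age genes, of the spread among old livers and of the splits were written down before their values were computed; the split of vehicle libraries and the run without 864 and 865 were added to the plan after other results were seen, and the shares of other genes beside that run were added after its value was seen.

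Interferon genes were higher in old than in young Myc livers under ruxolitinib. A hypothesis is that the drug acted less in old livers: the STAT5 targets Socs2 and Cish, which need JAK2, were also higher in old livers by 0.707 (exact permutation p = 0.011, chosen after the group means were seen), while under vehicle with mApple their old minus young difference was -0.0402 (exact permutation p = 0.962), but the list of 20 male-type STAT5 genes was lower in old livers, with a difference of -1.14 (exact permutation p = 1.08e-05) and under vehicle with mApple of -0.764 (exact permutation p = 0.0238), so STAT5 targets moved both ways and this stays undecided. Another is that old livers hold more immune cells, whose lists, of which 1 shares a member with the interferon list, were higher by 0.241 (exact permutation p = 0.0153). With the immune level as a covariate the interferon difference was 0.591 (permutation p = 0.00263) in place of 1.05. That level is a mean of marker lists, and adjusting for such an imperfect measure can leave a difference behind. Immune cells as the whole cause are therefore neither shown nor excluded. These 2 tests replaced an earlier pair on the interaction of age with the joint contrast, which decided neither explanation (Socs2 and Cish 0.748, permutation p = 0.391, and immune lists -0.196, p = 0.387); age itself, sequencing depth and time of day were not tested as causes and stay open.

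Genes that differ with age had values in the direction of age with ruxolitinib in the first batch (14.1% opposite) and against it in the second (84.1%). The second batch shares its vehicle libraries with the age comparison, which may give part of the 84.1%. Simulated groups without any age or drug effect, with the vehicle libraries shared, gave a median of 95%. The genes followed there had the smallest age p by noise alone. The 95% therefore shows that sharing can act, and is no measure of its part in the 84.1%. When those libraries were split between the contrasts the share ran from 46.5% to 74.5% and stayed over 50% in 5 of 6 splits, and Myc livers, which share no library with the age comparison, had 19.4% in the first batch and 68.3% in the second (59.0% for other genes), so sharing is not shown to be the whole cause. Leaving out libraries 864 and 865, which stand apart in the first batch, gave 32.2% beside 41.1% for other genes, so the bound of 50% set beforehand was not the value without change, and with each further library left out the 2 shares ran from 26.1% to 47.9% and from 40.9% to 45.0%, which leaves open whether these libraries are the cause there. A reversal of age differences by the drug is therefore neither shown nor excluded here.

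Among the 10 old Myc livers given ruxolitinib in the second batch, the interferon list varied widely, which might come from uneven drug action, immune cells or Myc. The level of Socs2 and Cish gave r = 0.422 (permutation p = 0.234, rho = 0.261, -0.509 without the farthest 2) and Myc gave r = -0.141 (permutation p = 0.707), so both remain undecided. Immune lists gave r = 0.785 (permutation p = 0.0104, adjusted p = 0.0311, rho = 0.648), as an immune cell source would predict. That value falls to 0.638 without the farthest 2 libraries (permutation p = 0.0971), so it rests in part on these.

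Group labels were exchanged within batches to see whether chance could give the counts of changed genes. For ruxolitinib in old mApple livers 2 of 100 arrangements, the real included, gave at least the real 53 genes, and the highest other gave 69: the share is under the bound of 5% set beforehand, but another grouping of these samples called more. For ruxolitinib in old Myc livers only the real arrangement reached its count, 1 of 100 (real 75, highest other 2). So it was for Myc under vehicle (2544 and 1) and under ruxolitinib (2012 and 0). The same held for age under Myc and ruxolitinib (4306 and 2) and the joint contrast in young livers (3524 and 7). With only 100 arrangements, chance is made unlikely for these counts, not excluded. In the joint contrast in old livers the share was also 1 of 100 (1496 and 545). For age in mApple vehicle livers 2 of 100 reached 145, with another at 342. For the joint interaction 3 of 100 reached 39, with another at 396, and for that of vector and drug 50 of 50 reached 0. Exchanged labels lose the drug or age effect too, so this cannot measure chance for interactions.

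For the interferon list, the share was under the bound of 5% in 6 comparisons, and in 2 of these another grouping lay farther from 0. The share of arrangements with a median as far from 0 was 2 of 100 for ruxolitinib in old mApple livers (real -0.81, farthest other 1.02) and 1 of 100 in old Myc livers (-0.94 and 0.78). It was 1 of 100 for Myc under vehicle (0.83 and 0.68) and 3 of 100 under ruxolitinib (0.78 and 0.80), 1 of 100 for age under Myc and ruxolitinib (1.29 and 1.04) and 1 of 100 for the joint contrast in young livers (-0.98 and 0.84). Chance cannot be excluded for age in mApple vehicle livers, 29 of 100 (0.55 and 0.78). Nor can it for the joint contrast in old livers, 65 of 100 (-0.171 and 0.996). These shares cannot measure chance for the interactions. The joint one had 17 of 100 (0.90 and 2.02), that of vector and drug 48 of 50 (0.02 and 1.25).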
